A study of Mus musculus with 8 samples.

How the data were processed

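RNA of brain endothelial cells, sorted by flow cytometry at postnatal day 8, was measured in 8 libraries, 4 from wild-type mice (WT) and 4 from mice with floxed Yap and Taz alleles and an endothelial inducible Cre (YT-ECKO). Per the labels' protocols, RNA was extracted with Trizol, 500 ng of total RNA went into each library, and a Lexogen Quant-Seq kit was used. Sequencing was done on a NextSeq 500, per the series' design text. The labels do not settle which part of each transcript the reads come from, and the strand setting is not given in the sources used here. Per the submitters' processing notes, Bowtie2 and edgeR were used with the mm10 genome build; their versions, the counting tool and the gene annotation are not given in the sources used here.

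The authors deposited 1 table per library with a gene symbol and a log2 value. No deposited value was below 0, and the unit was settled from the values. Returned to the linear scale, with a listed 0 kept at 0, each library summed to 10.3 to 10.9 M, and low values lay on whole multiples of a step that differed between libraries. Among values under 12, 88.3% to 100% lay within 0.1 of a whole multiple. The values were therefore read as log2 of read counts scaled to a common library size, and are called scaled reads on the linear scale. The library total divided by the step gave the depth implied for each library, 6.66 to 16.8 M reads. Rn45s, a ribosomal RNA precursor, is part of every total. Of the 24421 symbols per table, 27 differed between the tables because 5 of them held dates in place of symbols, and the 24394 symbols shared by all 8 were used.

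The design, the gene lists, the rule for the genes named and the alternatives listed first below were fixed before the data were examined. The planned test was one for read counts. Because the deposited values are log2 values, the test planned for that case was used in its place: limma with trended and robust moderation on log2(scaled reads + 128), without covariates. Voom was run only as an alternative. Fold changes on this scale understate the change of genes with low values. The pseudocount was chosen without looking at the contrast, as the smallest power of 2 whose ratio of highest to lowest SD over 8 bins of the mean lay within 1% of the lowest ratio (1.84 for 128 and 1.84 for 256). A gene was tested with at least 10 scaled reads in at least 4 libraries, which left 8706 genes. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Symbols were placed on GRCm38 with GENCODE release M21, which matched 8653 of the tested genes (99.4%), with older symbols matched through RefSeq synonyms; coordinates are those of the gene.

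Of 38 gene lists, 24 describe endothelial biology, 11 cell identity or other cell types and 3 RNA quality. Camera from limma was run on 36 of them with a preset correlation of 0.01, beside camera with an estimated correlation and fry, on the same log2(scaled reads + 128) values in place of the planned voom values. The list of mitochondrially encoded genes had no listed member, and the leukocyte list had 1 tested member. For lists of cell types the CPM, computed from scaled reads, were summed per library and compared by a two-sided exact permutation test. The genes named were Yap1, Wwtr1, Tead1, Tead2, Tead3, Tead4, Ctgf, Cyr61, Ankrd1 and Myc in every case; the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher group and no overlap between the groups, leaving out predicted genes and markers of other cell types; up to 4 genes with the smallest p of each biology list; and the 2 most abundant genes of each other list. With 4 libraries against 4 a two-sided exact permutation p cannot lie below 0.0286.

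The functions were tested on simulated libraries in which 200 genes were changed and 8649 genes passed the filter, drawn so that 1 molecule stood for 110 scaled reads. The simulated data had 12.6% of values at 0 against 11.3% in the real data. Of 91 tested genes changed 2-fold 5 were recovered, of 92 changed 4-fold 28 were recovered, 0 had the wrong direction, 1 unchanged gene was called, and 0 genes were called in libraries without any change.

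Count-based settings planned beforehand (size factors, 2 count tests and a surrogate variable) were not run. Alternatives covered scaling by library totals or upper quartile, no filter or a filter of 10 CPM in 4 libraries, voom with quality weights on rebuilt reads, the replicate number as a block, each library left out in turn, ribosomal protein and hemoglobin genes left out before scaling, a covariate for the erythroid list, a fold change minimum, and genes listed in any table. Added after seeing the data were pseudocounts of 1, 16, 64, 256 and 512, the log2 values as deposited, median-ratio scaling, array weights, the first residual principal component as a covariate, genes with a mean of at least 1000, the Rn45s share or Xist as a covariate, leaving out each library with the correlation of a list estimated, and list members with identical values counted once. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.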

Results

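RNA was profiled in endothelial cells sorted by flow cytometry from mouse brain at postnatal day 8. The series holds 2 groups of 4 libraries. WT libraries came from wild-type C57BL/6J mice. YT-ECKO libraries came from mice in which the tamoxifen-inducible VE-cadherin-CreERT2 driver acts on floxed alleles of Yap and Taz in endothelial cells. The mouse gene symbols are Yap1 for Yap and Wwtr1 for Taz, and the proteins are transcriptional co-activators of the Hippo pathway that act through TEAD factors. The question set by the design is which transcripts of the early postnatal brain endothelium differ between these groups. The Cre driver, the floxed alleles and any difference in strain background or tamoxifen treatment coincide with the deletion. They cannot be told apart from it here. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these samples. Sex-linked transcripts, given below, argue against a single mouse per library for several libraries.

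Each library listed 24421 gene symbols with a log2 value, and between 7538 symbols (YT-ECKO 1) and 9720 symbols (WT 1) were above 0. Returned to the linear scale, the values of a library summed to 10.3 to 10.9 M scaled reads. The spacing of low values implied 16.8 M reads for WT 1, 7.45 M for WT 2, 12.5 M for WT 3 and 11 M for WT 4. It implied 6.66 M reads for YT-ECKO 1, 12.1 M for YT-ECKO 2, 13.6 M for YT-ECKO 3 and 9.45 M for YT-ECKO 4. Genes above 0 numbered 8338 ± 553 (SD, n = 4) in YT-ECKO and 9342 ± 514 (SD, n = 4) in WT, a difference that did not pass a two-sided exact permutation test (p = 0.0857). A single read was worth 0.611, 0.866 and 0.9945 scaled reads in WT 1, 3 and 4, and 0.886 and 0.7655 in YT-ECKO 2 and 3. Its log2 would lie below 0, and no deposited value did, so such genes seem to be listed at 0 there. In WT 2, YT-ECKO 1 and YT-ECKO 4 (1.44, 1.55 and 1.15) they could stand above 0. The floor thus differs between libraries, for these numbers and for all shares at 0. Genes could be well detected in one library and listed at 0 in another of the same group. Of the genes that reached 100 scaled reads in some WT library, 33.4% were at 0 in another WT library, and the share was 45.3% within YT-ECKO. A value of 0 is therefore given as listed at 0, with the values of the single libraries.

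**Figure D1:**
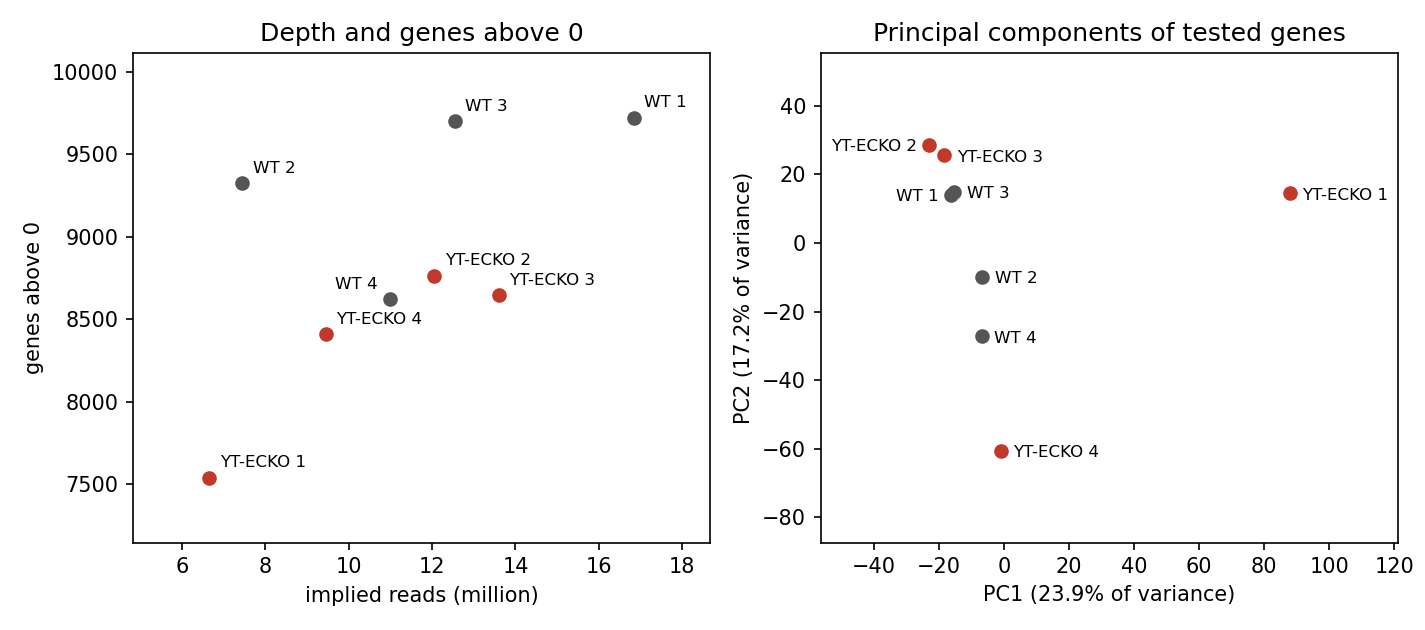
Left, genes above 0 against the number of reads implied by the spacing of low values (M), 1 point per library, WT in grey and YT-ECKO in red. The worth of a single read, and so the floor for a gene above 0, differs between libraries. Right, the first and second principal components of the tested genes on the log2(value + 128) scale, with 23.9% and 17.2% of the variance; YT-ECKO 1 stands apart on the first and YT-ECKO 4 on the second.

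Transcripts of both targeted genes were lower in the YT-ECKO libraries. Wwtr1 (chromosome 3, 57455649 to 57575910, minus strand, GRCm38) stood at 1335 ± 939 scaled reads in YT-ECKO against 6633 ± 1159 in WT (SD, n = 4 each), a log2 difference of -2.45 ± 0.41 (SE) on the log2(value + 128) scale with a limma adjusted p of 0.0113. Its values were 348, 2609, 1261 and 1124 in YT-ECKO 1 to 4 and 8220, 5906, 6756 and 5650 in WT 1 to 4. Yap1 (chromosome 9, 7931999 to 8004596, minus strand) stood at 327 ± 248 scaled reads in YT-ECKO against 1964 ± 613 in WT (SD, n = 4 each). Its values were 9.3, 605, 293 and 402 in YT-ECKO 1 to 4 and 2833, 1726, 1409 and 1887 in WT 1 to 4. The log2 difference of Yap1 was -2.39 ± 0.52 (SE) and did not pass the adjustment over all genes (limma adjusted p = 0.175). For each of these genes all 4 YT-ECKO libraries lay below all 4 WT libraries, which gave a two-sided exact permutation p of 0.0286, the smallest this design allows. Adjusted over the 6 tested genes among the 10 named in every case, that p was 0.0571 for both. None of the 6 could pass this adjustment unless most of them reached that smallest p, so it decides little. The unadjusted limma p was 3.9e-06 for Wwtr1 and 1.0e-04 for Yap1. The labels do not give the floxed exons, and reads from the part of a transcript outside the deletion count toward the same symbol, so these values do not measure the deletion itself. Wwtr1 lost its call when WT 1, WT 2 or YT-ECKO 4 was left out (adjusted p = 0.0755, 0.0580 and 0.0677), and with Xist added as a covariate (-2.38 ± 0.50, SE; adjusted p = 0.0950); the difference kept its sign in each case.

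**Figure D2:**
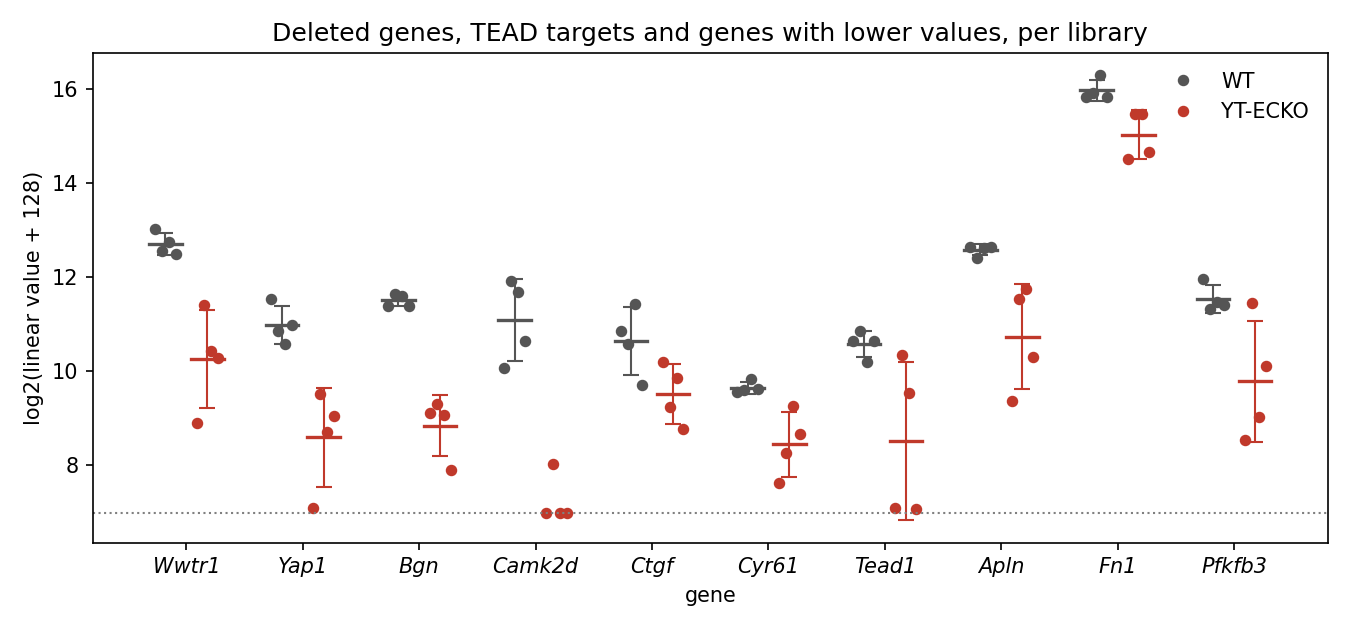
Values of 10 genes in each library on the log2(linear value + 128) scale, WT in grey and YT-ECKO in red, 1 point per library. Horizontal lines are group means and bars are 1 SD (n = 4), left out for Camk2d in YT-ECKO because 3 libraries are listed at 0; the dotted line marks a linear value of 0. For Wwtr1, Yap1, Bgn, Camk2d, Cyr61, Apln and Fn1 the points of the groups do not overlap.

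Over all 8706 genes tested, 3 fell and 0 rose in YT-ECKO (limma, Benjamini-Hochberg adjusted p under 0.05): Wwtr1, Camk2d and Bgn. Camk2d (chromosome 3, 126596302 to 126846326, plus strand), which encodes the delta chain of the calcium/calmodulin-dependent kinase II, was listed at 0 in YT-ECKO 1, 3 and 4 and at 133 scaled reads in YT-ECKO 2. In WT 1 to 4 it stood at 951, 3767, 3189 and 1468 scaled reads, and the fitted log2 difference was -3.83 ± 0.56 (SE; limma adjusted p = 0.00269). Bgn (chromosome X, 73483602 to 73495933, plus strand), which encodes the matrix proteoglycan biglycan, stood at 363 ± 174 scaled reads in YT-ECKO against 2789 ± 260 in WT (SD, n = 4 each), a log2 difference of -2.66 ± 0.44 (SE; limma adjusted p = 0.010). Left-out libraries changed the number of calls to 1 without WT 1 (Bgn adjusted p = 0.0575), 0 without WT 2 (Bgn 0.0591 and Camk2d 0.0580) and 6 without YT-ECKO 3. With Xist as a covariate 5 genes passed, of which Camk2d was the 1 shared with these 3 (Bgn adjusted p = 0.0950). The sums of 4 Y-linked genes also differed without overlap, with 486 to 1379 scaled reads in YT-ECKO and 4.43 to 471 in WT (exact permutation p = 0.0286), and the sex of the mice is not given in the labels. The gap was narrow, between 471 in WT 4 and 486 in YT-ECKO 1. No gene passed with a pseudocount of 1, on the log2 values as deposited, with no filter on low values, with voom on rebuilt reads, or when only genes with a mean of at least 1000 scaled reads were tested. At an unadjusted p under 0.05 there were 476 genes, 155 with higher and 321 with lower values in YT-ECKO, where 435.3 would be expected by chance. The groups did not overlap for 296 genes, or 3.40% of those tested, against 2.86% by chance. The median log2 difference of all tested genes was -0.09, and -0.22 with upper quartile scaling. Lower values were thus the more common direction over all tested genes. The numbers of lower members in the lists below stand against that background, since camera compares a list with the other genes. The 95% confidence interval of a gene reached a median of 0.84 log2 units to either side among the 1935 genes with a mean of at least 1000 scaled reads, and 1.10 among all tested genes. In simulated libraries with a median SD within groups of 0.66 log2 units, against 0.69 in the real ones, the test recovered 5.49% of genes changed 2-fold and 30.4% of genes changed 4-fold. A 2-fold difference of a single gene was thus mostly not detectable in these libraries.

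Known targets of YAP, TAZ and TEAD, a general list of 24 genes drawn from other cell types, did not pass the test as a list. Of the 16 list members tested, 10 had lower and 6 had higher values in YT-ECKO, with a median log2 difference of -0.34 (camera p = 0.0903, adjusted p = 0.361, and p = 0.246 with an estimated correlation). None of them passed when adjusted over the list alone or over all genes. Cyr61, now called Ccn1, encodes a secreted matricellular protein and stood at 253 ± 177 scaled reads in YT-ECKO against 680 ± 75.0 in WT (SD, n = 4 each), with no overlap between the groups (exact permutation p = 0.0286, adjusted 0.0571). Ctgf, now called Ccn2, stood at 658 ± 328 scaled reads in YT-ECKO against 1619 ± 803 in WT (SD, n = 4 each; exact permutation p = 0.0857, adjusted 0.103). The fitted log2 differences were -1.20 ± 0.54 for Cyr61 and -1.13 ± 0.48 for Ctgf (SE), with an unadjusted limma p of 0.0343 and 0.0260. Lats2, a Hippo pathway kinase that is also a YAP/TAZ target, had a difference of -1.32 ± 0.60 (SE) and was listed at 0 in YT-ECKO 1. Ankrd1 was listed at 0 in all 8 libraries. Myc was above 0 in WT 3 (222 scaled reads), YT-ECKO 2 (855) and YT-ECKO 3 (488) and at 0 in the other libraries, so it was not tested.

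Among TEAD and Hippo pathway genes, 9 of 16 had lower and 7 had higher values in YT-ECKO, and none passed over all genes or when adjusted over the list alone (list camera adjusted p = 0.991). Tead1, the most frequently detected TEAD factor here, stood at 9.3, 1175, 622 and 6.9 scaled reads in YT-ECKO 1 to 4 and at 1467, 1720, 1049 and 1468 in WT 1 to 4. Its log2 difference of -2.06 ± 0.64 (SE) had a limma adjusted p of 0.636 over all genes and 0.0611 over the list alone. The difference of Tead2 was -0.47 ± 0.66 (SE), with values that overlapped widely. Tead3 was listed at 0 in all 8 libraries. Tead4 was above 0 in WT 3, YT-ECKO 1 and YT-ECKO 3, at 146, 231 and 4.6 scaled reads.

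Of the lists describing sprouting, matrix and metabolism, 3 each had a single member that passed when adjusted over the list alone, and none that passed over all genes. The adjustment over a list alone was made for each list separately, without correction for the number of lists. Some such members can therefore be expected by chance. Apln (chromosome X, 48025146 to 48034853), which encodes the tip cell ligand apelin, stood at 1952 ± 1329 scaled reads in YT-ECKO against 6013 ± 473 in WT (SD, n = 4 each). Its log2 difference was -1.84 ± 0.42 (SE), with a limma adjusted p of 0.00629 over the tip cell list alone and 0.199 over all genes. Fn1 (chromosome 1, 71585520 to 71653200), which encodes fibronectin, stood at 34854 ± 12120 against 64478 ± 10440 scaled reads (SD, n = 4 each), a log2 difference of -0.94 ± 0.22 (SE). Its adjusted p was 0.00485 over the basement membrane list alone and 0.199 over all genes. All 4 YT-ECKO libraries lay below all 4 WT libraries for both Apln and Fn1. Pfkfb3 (chromosome 2, 11471433 to 11554077), a regulator of glycolysis, stood at 1075 ± 1120 against 2899 ± 670 scaled reads (SD, n = 4 each) with overlap, and its adjusted p was 0.0465 over the hypoxia and glycolysis list alone. Of the 26 tested tip cell genes, 18 had lower and 8 had higher values, a median log2 difference of -0.21 (camera adjusted p = 0.482). Of the 22 tested matrix genes, 14 had higher and 8 had lower values, a median of 0.18 (camera adjusted p = 0.357). Of the 24 tested hypoxia and glycolysis genes, 17 had higher and 7 had lower values, a median of 0.08 (camera adjusted p = 0.482).

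Barrier genes gave no call, either singly or as a group. Of the 18 tested genes of junctions and the blood-brain barrier, 10 had higher and 8 had lower values in YT-ECKO, with a median log2 difference of 0.03 (camera adjusted p = 0.493). Cldn12, which encodes a claudin and had the smallest p of the list, stood at 74.0, 287, 1443 and 891 scaled reads in YT-ECKO 1 to 4 and at 661, 5.8, 3.5 and 0 in WT 1 to 4, a log2 difference of 1.56 ± 0.71 (SE; limma adjusted p = 0.687 over the list alone). The tight junction gene F11r stood at 4543 ± 1813 scaled reads in YT-ECKO against 3244 ± 752 in WT, and Cgnl1, which encodes paracingulin, at 8397 ± 4540 against 9243 ± 2055 (SD, n = 4 each). The 95% interval of the log2 difference ran from -0.28 to 1.12 for F11r and from -0.99 to 0.41 for Cgnl1. Ocln, which encodes occludin, was listed at 0 in YT-ECKO 1 and stood at 311, 248 and 185 scaled reads in YT-ECKO 2 to 4, against 318, 279, 179 and 686 in WT 1 to 4. Of the 22 tested transporter genes, 11 had higher and 11 had lower values, with a median of -0.03 (camera adjusted p = 0.902). The amino acid transporter gene Slc38a5 stood at 2698 ± 1562 against 5560 ± 1541 scaled reads (SD, n = 4 each), with an adjusted p of 0.115 over the transporter list alone. Of 9 tested genes of fenestrated or permeable endothelium, 5 had higher and 4 had lower values, with a median of 0.12 (camera adjusted p = 0.902). For the Wnt/beta-catenin list, 16 of 21 tested genes had lower values and the median was -0.16 (camera adjusted p = 0.902), while Lef1, a transcription factor of that pathway, stood at 3465 ± 907 in YT-ECKO against 1531 ± 1169 in WT (SD, n = 4 each; adjusted p = 0.0859 over the list alone).

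Arterial and venous genes, signalling pathways and proliferation genes also gave no list below an adjusted p of 0.05. Of 20 tested arterial genes, 11 had higher and 9 had lower values, with a median of 0.19 (camera p = 0.0355, adjusted p = 0.357, and p = 0.143 with an estimated correlation). Gja4, which encodes connexin 37, stood at 2377 ± 444 scaled reads in YT-ECKO against 1027 ± 208 in WT (SD, n = 4 each), without overlap between the groups, and its adjusted p was 0.133 over the list alone. Of 13 tested venous genes, 6 had higher and 7 had lower values, a median of -0.05 (camera adjusted p = 0.902). Lower values were found for 9 of 15 Notch genes (median -0.27, camera adjusted p = 0.902), 11 of 16 VEGF and Tie2 genes (median -0.18, camera adjusted p = 0.464) and 14 of 21 BMP and TGF-beta genes (median -0.10, camera adjusted p = 0.902). Ptprb, which encodes the vascular endothelial protein tyrosine phosphatase, stood at 2424 ± 751 against 4887 ± 638 scaled reads (SD, n = 4 each) without overlap, with an adjusted p of 0.0731 over the VEGF list alone. Lower values were also found for 13 of 23 DNA replication genes (median -0.10, camera adjusted p = 0.744) and 14 of 20 mitosis genes (median -0.37, camera adjusted p = 0.415). Top2a was listed at 0 in YT-ECKO 1 and stood at 129, 517 and 44.8 scaled reads in YT-ECKO 2 to 4, against 222, 431, 572 and 399 in WT 1 to 4.

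**Figure D3:**
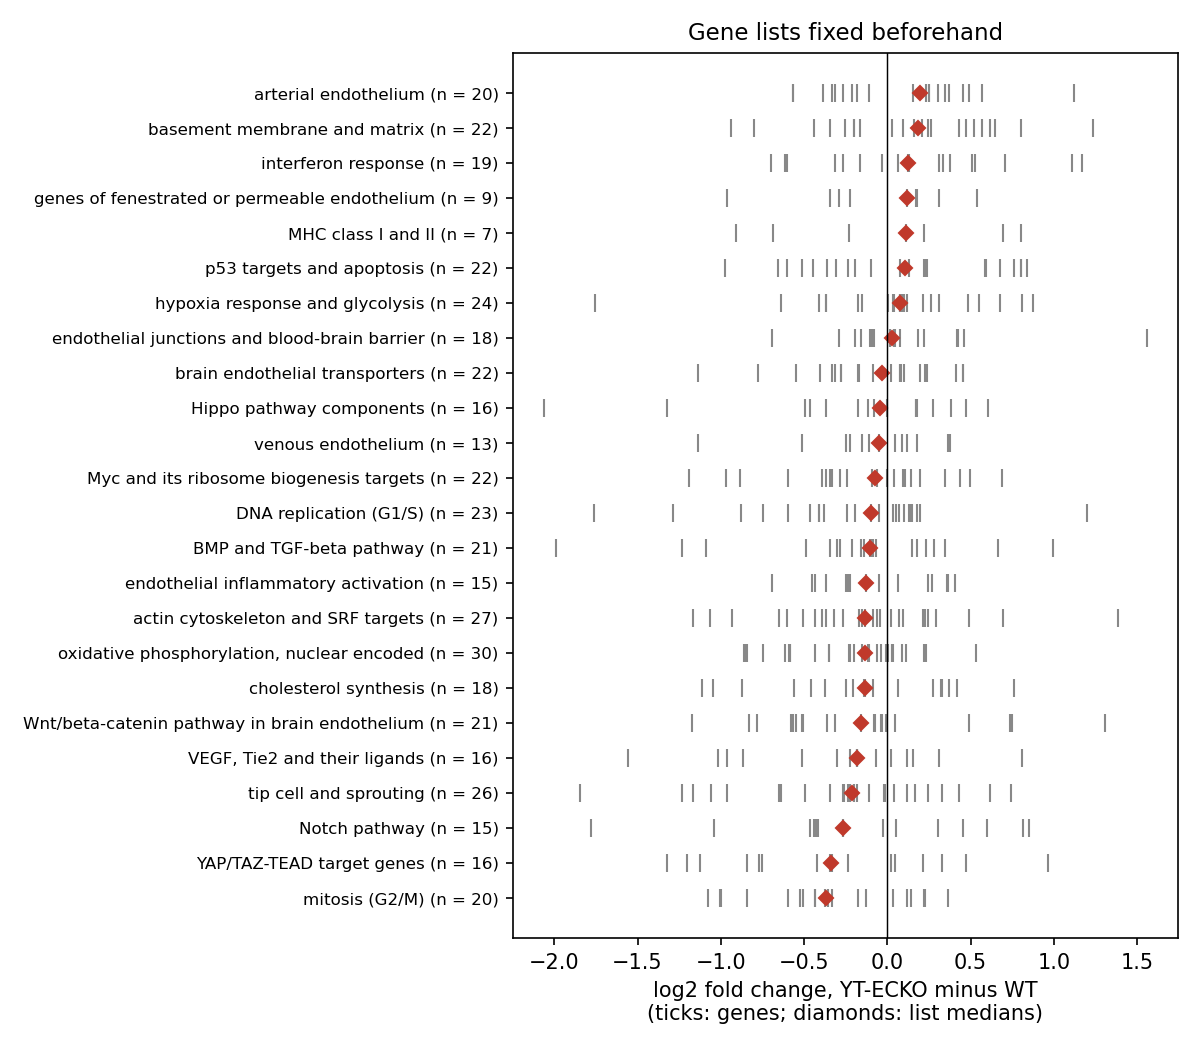
Log2 differences (YT-ECKO minus WT) of the tested members of the 24 biology lists fixed beforehand; each tick is a gene, each diamond the median of its list, and n the number of members tested. Medians ran from -0.37 for mitosis to 0.19 for arterial endothelium; with upper quartile scaling 5 of the 24 medians changed sign.

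The remaining biology lists were spread around 0 as well. Medians were -0.08 for 22 Myc targets, -0.13 for 27 genes of the actin cytoskeleton, -0.13 for 30 genes of oxidative phosphorylation and -0.13 for 18 genes of cholesterol synthesis. They were -0.13 for 15 genes of inflammatory activation, 0.12 for 19 interferon genes, 0.11 for 7 MHC genes and 0.10 for 22 p53 and apoptosis genes. Camera adjusted p-values of these lists lay at or above 0.493. Of the 36 lists tested, 0 passed an adjusted p of 0.05, and 4 had an unadjusted camera p under 0.05 (3 when hemoglobin genes with identical values are counted once). The lowest adjusted p was 0.357 with the preset correlation, 0.814 with an estimated correlation, 0.654 with fry for one direction and 0.562 with fry for either direction. In simulated data, 5 of 5 lists raised 2-fold and 0 of 30 unshifted lists were called. Simulated genes were drawn independently and all members of a raised list were shifted alike. In the real data the estimated correlation reached 0.61 for ribosomal protein genes, so the simulated result does not give the error rate or power for these lists. The ribosomal protein list passed without WT 1, WT 3, YT-ECKO 1 or YT-ECKO 4 (camera adjusted p = 0.00134, 0.00272, 0.0117 and 0.00325), in each case with lower values in YT-ECKO. Without WT 4 or YT-ECKO 3 its direction turned to higher values (camera adjusted p = 0.671 and 0.670), and between the 4 libraries with the lower and the 4 with the higher Rn45s share, 2 of each group in each set, its median differed by -0.71. With the same test the erythroid list passed without YT-ECKO 2 with higher values (camera adjusted p = 0.00151; 0.548 when hemoglobin genes with identical values are counted once). With an estimated correlation 0 lists passed when any of the 8 libraries was left out, and the adjusted p of the 5 cases that had passed was, in the same order, 0.922, 0.969, 0.858, 0.981 and 0.939.

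Markers of other cell types, apart from erythroid genes, were low beside endothelial ones. No difference in summed CPM between the groups passed an exact permutation test for any of these lists, the erythroid one included. The 25 pan-endothelial genes summed to 23213 ± 2734 CPM in YT-ECKO and 23077 ± 696 in WT (SD, n = 4 each; exact permutation p = 0.943). Their median log2 difference was 0.02 as deposited and -0.18 with upper quartile scaling. Pericyte markers summed to 69.4 ± 56.5 CPM in YT-ECKO and 79.3 ± 64 in WT, smooth muscle markers to 308 ± 188 and 469 ± 162, and fibroblast markers to 467 ± 267 and 737 ± 228 (SD, n = 4 each; exact permutation p = 0.800, 0.257 and 0.171). All 12 tested genes of these 3 lists had lower values in YT-ECKO (camera p = 0.0489, 0.0793 and 0.0746, adjusted p = 0.357 for each, and p = 0.245, 0.125 and 0.166 with an estimated correlation), beside the lower values of Bgn and Fn1, which mural cells and fibroblasts also express. Sums in YT-ECKO and WT were 130 and 148 CPM for microglia, 1164 and 1152 for astrocytes, 110 and 37.7 for neurons, 72.5 and 43.0 for oligodendrocytes, 30.3 and 22.5 for leukocytes and platelets, and 420 and 550 for choroid plexus and ependyma. Erythroid genes summed to 4443 ± 1914 CPM in YT-ECKO and 3021 ± 1228 in WT (SD, n = 4 each; exact permutation p = 0.314), most of it hemoglobin. Hba-a1 and Hba-a2, Hbb-b1 and Hbb-bs, and Hbb-b2 and Hbb-bt carried identical values in every library, so 6 of the 10 tested erythroid members are 3 values entered 2 times in these sums and in the list test. Counted once, the sums were 2300.4 ± 976 CPM in YT-ECKO and 1607 ± 603 in WT (SD, n = 4 each; exact permutation p = 0.314).

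The Rn45s share and the ribosomal protein sum varied within groups more than between them. Rn45s, the 45S ribosomal RNA precursor, took 8.39% to 14.8% of a library's scaled reads, with 12.1% ± 2.66 in YT-ECKO and 11.7% ± 2.30 in WT (SD, n = 4 each; exact permutation p = 0.829). Ribosomal protein genes summed to 21576 ± 6606 CPM in YT-ECKO and 25496 ± 8587 in WT (SD, n = 4 each), and 69 of 85 tested members had lower values (camera adjusted p = 0.357). Of 26 tested immediate-early and heat shock genes, 17 had higher values in YT-ECKO (camera p = 0.0220, adjusted p = 0.357, and p = 0.293 with an estimated correlation). Mitochondrially encoded genes were absent from the symbols listed. Correlations between libraries over the tested genes were 0.782 to 0.839 within WT, 0.684 to 0.774 within YT-ECKO and 0.700 to 0.809 between the groups. Those within YT-ECKO all lay below those within WT. Of genes with a mean of 100 to 300 scaled reads, 20.1% to 36.6% were at 0 in a YT-ECKO library and 10.3% to 20.4% in a WT library. Whether this bears on the lower values in YT-ECKO was not tested. The 4 libraries with the lower Rn45s share (WT 1, WT 3, YT-ECKO 2 and YT-ECKO 3) were also the 4 deepest, and the difference between YT-ECKO and WT was computed within each set of 4. With 2 libraries per group in each set, the log2 difference was -1.96 in the lower and -2.94 in the higher set for Wwtr1, -1.94 and -2.84 for Yap1, -2.30 and -3.01 for Bgn, and -3.37 and -4.28 for Camk2d. It was -0.99 and -2.70 for Apln, -0.59 and -1.29 for Fn1, -0.47 and -3.66 for Tead1, -1.48 and -2.03 for Pfkfb3, and -0.94 and -1.46 for Cyr61, while Ctgf was further below 0 in the lower set with -1.60 and -0.66. For Wwtr1, Yap1, Bgn, Camk2d, Apln, Fn1 and Cyr61 the groups do not overlap. Their negative sign in both sets was thus fixed in advance, and only the sizes differ between the sets.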

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

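All tests in this part that weigh an explanation were chosen after the results were seen, except the thinning of reads. For Bgn and sex-linked expression, Xist was first added as a covariate, which ended the call of Bgn, and the comparison within a shared range of Xist was chosen after that. In each group of 4, the distance of the outermost library from its nearest neighbour was compared with the whole range for 117 named genes, on the log2(value + 128) scale, and for 3 library measures. Of 240 sets of 4 values, 16 passed the 95% limit for 4 values (0.829), and 12 would be expected by chance, since about 1 in 20 passes. No library measure did.

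Most of these sets came from genes listed at or near 0 in the other libraries of the group. The ratio was 1 for Camk2d, Birc3 and Usp18 in YT-ECKO, where YT-ECKO 2 held 133, 174 and 25.7 scaled reads and the others 0, for Esm1 in YT-ECKO (168 scaled reads in YT-ECKO 1) and for Rrp12 in WT (46.8 scaled reads in WT 3). It was 0.976 for Cldn12 (661 scaled reads in WT 1), 0.987 for Clspn (178 in WT 1) and 0.973 for Plod2 (98.2 in WT 1), all in WT. It was 0.973 for Dkk2 (76.2 scaled reads in YT-ECKO 2), 0.983 for Rgs5 (419 in YT-ECKO 3), 0.978 for Srm (508 in YT-ECKO 2) and 0.905 for Tap1 (258 in YT-ECKO 3), all in YT-ECKO.

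For genes measured in every library of the group the outlying values were lower than the rest. Apln in WT had a ratio of 0.853, with 5312 scaled reads in WT 2 against 6144 to 6299 in the other libraries. In YT-ECKO, Cdkn1a had 0.830, with 591 scaled reads in YT-ECKO 1 against 3428 to 4801. Notch4 had 0.842, with 633 in YT-ECKO 1 against 1836 to 2218, and Mvk had 0.846, with 378 in YT-ECKO 2 against 942 to 1099.

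Camk2d was at 0 in 3 of 4 YT-ECKO libraries. Many genes are at 0 in some libraries of a group and well above 0 in others, and a loss of transcripts at random was weighed as an explanation. Among the 1247 genes with at least the lowest WT value of Camk2d (951 scaled reads) in all 4 WT libraries, 0.0802% to 0.722% were at 0 in a YT-ECKO library, and Camk2d alone was at 0 in 3 or more. From these rates 5.46e-05 genes would be expected, which argues against independent loss as the cause, and 0 of the 1128 genes as abundant in all YT-ECKO libraries were at 0 in 3 or more WT libraries. The 1247 genes had no upper limit of abundance. Of the 1343 genes with a mean of 1000 to 3000 scaled reads, 0.521% to 2.16% were at 0 in a YT-ECKO library, so the expected number is a low estimate. A loss that is not independent between libraries and the genotype stay open.

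Bgn lay below every WT library in all 4 YT-ECKO libraries, and mural cells and fibroblasts express it too. The markers of pericytes, smooth muscle and fibroblasts summed to 8969 ± 4260 scaled reads in YT-ECKO and 13730 ± 3945 in WT (SD, n = 4 each), a ratio of 0.653 against 0.130 for Bgn itself. Bgn divided by that sum still differed by -2.43 log2 units (exact permutation p = 0.0286). Bgn was picked for its lack of overlap, so this p adds little. The ratio was 0.112, 0.036, 0.047 and 0.012 in YT-ECKO 1 to 4 and 0.151, 0.296, 0.288 and 0.148 in WT 1 to 4. A lower share of cells with these markers thus leaves most of the change unaccounted for in YT-ECKO 2 to 4, while YT-ECKO 1 lay close to WT 1 and WT 4. Apod and Smtn (5370 and 4157 scaled reads in WT) weigh most in the sum, so cells that they follow poorly are not covered. Bgn is X-linked and the mean of Xist was lower in YT-ECKO. Among the 4 libraries with Xist in the range shared by both groups (4611 to 8434 scaled reads) the difference was -2.31. Bgn stood at 3066 and 2565 scaled reads in WT 2 and WT 4 against 425 and 509 in YT-ECKO 1 and YT-ECKO 2. The sums of 4 Y-linked genes were higher in YT-ECKO, without overlap but by a narrow gap (4.43 to 471 in WT, 486 to 1379 in YT-ECKO). The sex of the mice is not given, so a different sex mix cannot be told apart from the genotype. With Xist as a covariate the change of Bgn went from -2.66 ± 0.44 to -2.20 ± 0.47 (SE) and its adjusted p to 0.0950, because the effect shrank and its SE grew, while Apln went from -1.84 ± 0.42 to -1.65 ± 0.50; the sex mix and a lower level in the endothelial cells after deletion stay open.

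The 3 genes called were set against the other splits of the 8 libraries into 4 and 4. Of the 35 splits, 2 gave at least 3 calls, the real one included and the highest of the others being 3 (WT 1, WT 3, WT 4 and YT-ECKO 2 on one side), so that chance cannot be excluded for the count as a whole. For the lists, where 0 passed in camera or fry and 4 had an unadjusted camera p under 0.05, this comparison decides nothing, because each of the 35 splits gives at least 0; the highest number of lists with an adjusted p under 0.05 in another split was 5.

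The split of WT 1, WT 3, YT-ECKO 2 and YT-ECKO 3 against the rest gave 841 genes at an unadjusted p under 0.05 and 1 call, against 476 and 3 in the real split, which points to a structure of the samples that crosses the genotypes. These 4 libraries had the lower Rn45s shares (8.39% to 11.8% against 13.1% to 14.8%) and the higher depths (12.1 to 16.8 against 6.66 to 11 M reads). Among 1927 abundant genes the difference between these sets rose with the length of the longest transcript (Spearman rho 0.491 across genes, which are not independent replicates), and at 0.461 without ribosomal protein genes it was above the 0.364 of any other split over all abundant genes, consistent with a length bias of RNA or library preparation. Thinning every library to 6.66 M reads left rho at 0.491, but thinning hardly alters genes this abundant and so decides nothing, and because the sets also divide by depth a difference in depth cannot be told apart from them. The genotype contrast had a rho of 0.0604. The sets hold 2 libraries of each group, so the set as a covariate leaves every fitted difference unchanged and alters only its SE. With this covariate the 3 calls remained and Fn1 joined them, which does not test whether the structure produced them. No biological explanation of the sets was tested.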

How the results depend on the processing

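The pseudocounts, the log2 values as deposited, median-ratio scaling, array weights, the residual component, the minimum mean of 1000, the Rn45s share, Xist as a covariate, left-out libraries with an estimated list correlation and list members with identical values counted once were tried after seeing the data. The planned size factors, count tests and surrogate variable were not run, also not on the rebuilt reads used for voom. Wwtr1, Camk2d and Bgn were each called again with scaling by totals, upper quartile or median ratios, at least 10 CPM in 4 libraries, ribosomal protein and hemoglobin genes left out, the erythroid covariate, a minimum log2 fold change of 1, genes listed in any table, array weights and a pseudocount of 64. The number of calls was 0 with no filter, voom, a pseudocount of 1, the deposited log2 values or a minimum mean of 1000, and 5 with the residual component (Apln and Yap1 added) or the replicate number as a block (Fn1 and Sh3kbp1 added). With Xist as a covariate 5 genes passed, Camk2d and 4 others (Dclk2, Pla2g12a, Rpl34 and Tubgcp4, named after their values were seen). Residuals of libraries with the same number correlated at -0.030, -0.043, 0.066 and 0.076, so the numbers were not taken to pair samples. Leaving out 1 library gave 0 calls (without WT 2) to 6 (without YT-ECKO 3), with 1 without WT 1, and 0 to 1 lists (0 with an estimated correlation, 0 to 1 with members of identical values counted once). The erythroid covariate counts such members each. Wwtr1 missed the threshold at -2.45 with no filter (adjusted p = 0.854) and with a minimum mean of 1000 (0.0989), at -2.38 with voom (0.244) and with Xist as a covariate (0.0950), at -2.62 with a pseudocount of 1 (0.263) and with the deposited values (0.250), and at -2.60 with a pseudocount of 16 (0.0822). Over all 30 alternatives its adjusted p ran from 0.000848 to 0.854, and with 1 library left out its difference ran from -2.83 to -1.99. Yap1 passed with the residual component (-2.39, adjusted p = 0.0232; 0.0232 to 0.905 over all alternatives) and ran from -2.70 to -1.89 with 1 library left out. Of 117 named genes tested, 104 kept their direction in the alternatives that tested them, 24 to 30 per gene; 55 genes were tested in all 30. The other 13 reversed at least once: Cnp (-0.92 with voom, -0.020 with a pseudocount of 1), Enpp2 (0.092 with Xist as a covariate), Esam (-0.16 with upper quartile scaling), Meg3 (-0.32 with voom) and Sparcl1 (-0.20 with upper quartile scaling, -0.046 with voom, -0.010 with the erythroid covariate, -0.042 with array weights), and with 1 library left out Cgnl1 (-0.58 to 0.060), Cnp (-0.24 to 0.66), Dbi (-0.28 to 0.12), Egfl7 (-0.18 to 0.078), Enpp2 (-0.42 to 0.036), Esam (-0.023 to 0.11), Laptm5 (-0.0094 to 0.63), Meg3 (-0.027 to 0.96), Nr2f2 (-0.039 to 0.71), Rplp1 (-0.32 to 0.11), Sparcl1 (-0.13 to 0.17), Tead2 (-0.97 to 0.30) and Ttr (-1.67 to 0.078). Except for the smaller number of libraries when 1 was left out, the cause was not tested. Implied depths of 6.66 to 16.8 M reads and the many values of 0 limit what was measured for genes with low values.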

Other observations

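The tests of sex-linked transcripts in this part were chosen after the values were seen. Transcripts linked to sex varied within both groups, and their means differed between the groups. Xist stood at 17929, 8255, 22931 and 4611 scaled reads in WT 1 to 4 and at 6299, 8434, 4150 and 6.9 in YT-ECKO 1 to 4. The Y-linked Ddx3y stood at 131, 1.5, 275 and 354 in WT 1 to 4 and at 15.5, 708, 405 and 506 in YT-ECKO 1 to 4. Eif2s3y stood at 0, 0, 140 and 117 in WT and 0, 249, 0 and 313 in YT-ECKO, Kdm5d at 0, 1.5, 0 and 0 and at 0, 0, 201 and 250, and Uty at 0, 1.5, 0 and 0 and at 471, 292, 0 and 310, in the same order. These 4 Y-linked genes summed to 930 ± 449 in YT-ECKO and 255.6 ± 224 in WT (SD, n = 4 each), with no overlap (exact permutation p = 0.0286, the smallest this design allows). The gap was narrow, with 471 in WT 4 and 486 in YT-ECKO 1, of which Uty alone made up 471. Xist was 4723 ± 3598 in YT-ECKO and 13432 ± 8467 in WT, and Ddx3y was 408 ± 291 and 190 ± 156 (SD, n = 4 each; exact permutation p = 0.143 and 0.371). The labels do not give the sex of the mice. Xist stood beside both Ddx3y and Eif2s3y in WT 3, WT 4 and YT-ECKO 2, which argues against a library from a single mouse in these cases. Carry-over between libraries was not tested.

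Of the 10 genes with the lowest p, 3 are X-linked (Bgn, Sh3kbp1 and Apln). This was noticed from the values, and 0.309 X-linked genes would be expected among 10 from their share of the tested genes. A hypergeometric exact test across genes, chosen after the values were seen, gave an exact p of 0.00298. Genes are not independent replicates, so this p adds little. Sh3kbp1 was chosen for naming after its values were seen. The 269 tested X-linked genes had a median log2 difference of -0.11, against -0.09 for autosomal genes.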
